A study of Mus musculus with 8 samples.

How the data were processed

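RNA from 8 mouse salivary gland samples was hybridised to 1-colour Agilent whole mouse genome arrays (design 014868). Per the labels, total RNA was extracted with Trizol and 300 ng was labelled with the Quick-Amp 1-colour kit. The samples were untreated tumour (n = 2), tumour after 3 days of rapamycin (n = 1), tumour after 14 days (n = 2), parotid gland (n = 2) and submandibular gland (n = 1). The labels do not say whether arrays of a group came from separate animals, so each p-value of a gene measures only the spread between these samples.

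Per the file headers, the authors read the arrays with Feature Extraction 10.7.3.1, which gave for each spot a background-subtracted and spatially detrended intensity, its mean pixel intensity, the local background and quality calls. These deposited intensities were not scaled between arrays. The table of values deposited by the authors is on a log2 scale with medians of 5.52 to 5.57 and a shared maximum of 18.96 on all arrays, and each column correlated at 0.971 to 0.980 with its own array. It was used as an alternative only. Probe positions are on the mm8 assembly.

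Each array held 43379 non-control spots of 41174 probes. Genes were named through the RefSeq symbols for 23374 probes and through a synonym for 2919, and 14881 kept the name in the files. Spots that the scanner software called non-uniform or outliers were left out, which removed 273 of the kept probes, and the day 3 array had 791 non-uniform spots against 5 to 51 elsewhere. A probe was kept if it was well above background on every array of at least 1 group, which left 24552 probes. The brightest probe stood for each gene, giving 16362 genes, of which 11021 were well above background on all 8 arrays and 3009 had clone-type names. Of 532 list symbols 528 were found, and Klk1b5, Klk1b22, Irs2 and Pck1 were not. No spot was saturated.

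The log2 processed signal minus the 75th percentile of its array was fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 5 groups over all 8 arrays and an intensity trend in the variance prior. The fit had 3 residual degrees of freedom and a prior of 3.28. The single arrays of day 3 and of submandibular gland were assumed to vary like the replicated groups. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, with a threshold of 0.05 and no minimum fold, and they are two-sided. The comparisons were untreated tumour with parotid, day 14 with untreated tumour, day 3 with untreated tumour, day 14 with day 3, day 14 with parotid, untreated tumour with submandibular gland, and submandibular gland with parotid. All 7 share the pooled spread.

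The 28 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. No list call of any comparison held with an estimated correlation. The lists cover gland cell types, proliferation, Wnt targets, PI3K signalling, FOXO targets, metabolism, stress responses, immune and stromal cells, fat, muscle, nerve and sex chromosomes. The threshold, comparisons, lists, other ways of processing and rule for naming genes were chosen before the data were examined.

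By that rule, the genes named for untreated tumour against parotid and day 14 against untreated tumour were the 8 largest rises and 8 largest falls among those past the threshold whose values did not overlap between the groups, plus from each list the 2 members past the threshold with the largest change. For the other comparisons they were 4 rises, 4 falls and 1 member per list. Clone-type names were passed over, and Akt1, Akt2, Apc, Ctnnb1 and Mtor were always given. Some further genes that the rule names, and tests on them, are not reported here. Ano1 was named outside the rule, after its values were seen. A gene counted as well above background on an array if any of its probes was. Where it was so on no array of a group, a fold is given only as a bound. Where it was so on 1 of 2 arrays, the log2 difference over all arrays is given and the text says so.

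The correlation between tumour and day 14 differences was set against 200 simulations of unchanged groups that share the untreated tumour arrays. Overlaps of called genes were set against 200 more, in which lists of the same sizes were taken by rank of the moderated t. These were added after the results were seen. Simulated data had 50 genes shifted per size, 2 arrays against 2. Called were 88% of those shifted by 4 on the log2 scale, 38% by 2, 0% by 1 and 0.0371% of unshifted genes. With few shifted, the rates can be too low where many genes differ.

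The other ways of processing tried were normexp background correction with an offset of 50, quantile normalization, the deposited log2 values, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, no intensity trend, slide as a fixed or random block, slide 1 alone, only the arrays of the groups compared, at least 2-fold, and leaving out each replicate. Chosen after seeing the data were keeping the outlier spots, list counts without each replicate and by slide, and differences of single arrays on slide 2. The last are not reported, since these arrays are also in the fit. Input was read with the R package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.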

Results

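Gene expression was measured in 8 samples of mouse salivary gland tissue on 1-colour Agilent whole genome arrays. The tumours were salivary gland tumours induced by AKT, a kinase of the PI3K pathway, and some had been treated with rapamycin, an inhibitor of the mTOR kinase. The groups were untreated tumour (n = 2), tumour after 3 days of rapamycin (n = 1), tumour after 14 days of rapamycin (n = 2), normal parotid gland (n = 2) and normal submandibular gland (n = 1). The arrays lay on 2 slides. Slide 1 held both untreated tumours, parotid replicate 1 and day 14 replicate 1, and slide 2 held the other arrays.

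The 75th-percentile signal was 966 and 972 in the untreated tumours, 730 at day 3, 177 and 236 at day 14, 384 and 145 in the parotid glands and 277 in the submandibular gland. Between 43.2% and 58.4% of the spots of an array were well above background, with the lowest share in the submandibular gland and the highest in untreated tumour replicate 2. The number of arrays limited the precision. Across genes, which are not independent replicates, the untreated tumours correlated at r = 0.985 with each other and at 0.972 and 0.966 with the day 3 array. The day 14 arrays correlated at 0.987 with each other, at 0.911 to 0.920 with the parotid arrays, at 0.900 to 0.911 with the submandibular array and at 0.771 to 0.787 with the untreated tumours.

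The arrays differed in sex-linked transcripts. Xist, the transcript of the inactive X chromosome, was at a log2 signal of 3.097 to 4.46 relative to the 75th percentile in untreated tumour replicate 2, parotid replicate 1, the submandibular gland and the day 3 tumour, and the Y-linked genes averaged −7.59 to −5.02 there. In untreated tumour replicate 1 and parotid replicate 2, Xist was not well above background (−5.45 and −5.17) and the Y-linked genes averaged 0.15 and 0.43. Both day 14 arrays held Xist well above background (−2.10, −2.40) and Y-linked signal (0.70, 0.45), as mixed sexes could give, and may not be independent. Untreated tumours and parotids each held 1 array of either earlier pattern.

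The comparison of untreated tumour with normal parotid gland asked how the tumours differ from normal tissue. Secretory transcripts of the gland were far lower in the tumours. Klk1 (−13.82 ± 1.21, adjusted p = 0.000583) and Klk1b4 (−13.31 ± 0.84, adjusted p = 0.000238), kallikrein proteases of salivary ducts, fell, as did Prb1 (−13.20 ± 1.42), a proline-rich salivary protein, and Smr3a (−12.81 ± 2.30). Transcripts of cell division and Wnt signalling rose, among them Plk1 (5.54 ± 0.56, adjusted p = 0.000965), a mitotic kinase, Tpx2 (5.59 ± 0.82, adjusted p = 0.00347), a spindle protein, and Sp5, a transcription factor induced by Wnt, which was at least 326-fold higher (adjusted p = 8.99e-05). Values after ± are standard errors, this comparison set 2 arrays against 2, and folds given as "at least" compare a group with, on each array of the dim group, the lowest well-above-background signal or the gene's own signal where that was higher. Klk1, Klk1b4, Prb1 and Smr3a were well above background on only 1 of the 2 tumour arrays, and Tpx2 on 1 of the parotid arrays, so the sizes of their changes are uncertain. The tumour arrays differed widely in these salivary transcripts, with standard deviations of 2.95 for Klk1, 1.86 for Klk1b4, 3.52 for Prb1 and 5.70 for Smr3a. Smr3a was at −8.78 without untreated tumour replicate 1 and at −16.84 without replicate 2.

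Other rises were in Bpifb9a (at least 2576-fold higher) and Bpifb5 (11.02 ± 0.44), secreted proteins of the BPI fold family, Wif1 (at least 578-fold higher) and Dkk2 (at least 339-fold higher), secreted regulators of Wnt signalling, Prss56 (at least 224-fold higher), a serine protease, Slc30a2 (at least 300.3-fold higher), a zinc transporter, and Tmc5 (at least 159-fold higher). Further falls were in Wfdc12 (−13.25 ± 1.41), Cldn22 (at least 4426-fold lower), Cst10 (−13.09 ± 2.43), a cystatin, and Crisp1 (−12.85 ± 1.26). Wfdc12, Cst10 and Crisp1 were well above background on 1 of 2 tumour arrays, with standard deviations of 3.44, 5.98 and 3.11, and Bpifb5 on 1 of 2 parotid arrays. Cst10 was at −8.86 without untreated tumour replicate 1 and at −17.32 without replicate 2. limma called 6389 of 16362 genes, 3062 higher and 3327 lower in tumour, and 5615 by at least 2-fold. Parotid was dim for 596 called genes, tumour for 540 and both for 161. The 161 and 60 more had no fold. The count was 3174 without untreated tumour replicate 1, 3034 without untreated tumour replicate 2, 5106 with slide as a fixed block and 7539 within slide 1.

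The gene lists showed the same contrast. Of 22 acinar secretory genes, over all genes 0 rose and 20 fell, 0 and 21 adjusted over the list alone. Their median was −8.99 (camera adjusted p = 1.85e-11, adjusted p = 0.234 with an estimated correlation). Prpmp5 (at least 3173-fold lower) was among those lower. For the 18 submandibular granular duct and mucous genes, over all genes 0 rose and 15 fell, 0 and 16 adjusted over the list alone. Their median was −9.23, or −7.49 with dim members at their bound (camera adjusted p = 9.89e-09, adjusted p = 0.412 with an estimated correlation). All 33 proliferation genes were higher: over all genes 33 rose and 0 fell, 33 and 0 adjusted over the list alone. Their median was 4.20, or 4.03 with dim members at their bound (camera adjusted p = 4.44e-15, adjusted p = 0.473 with an estimated correlation). In the list of 21 Wnt targets, over all genes 16 rose and 1 fell, 16 and 1 adjusted over the list alone. Their median was 4.07, or 3.27 with dim members at their bound (camera adjusted p = 3.92e-08, adjusted p = 0.234 with an estimated correlation). Cell cycle inhibitors and p53 targets (14 tested) rose on balance: over all genes 7 rose and 1 fell, 7 and 2 adjusted over the list alone. Their median was 0.75 (camera adjusted p = 0.0186, adjusted p = 0.412 with an estimated correlation). Cdkn1a (5.16 ± 0.27) and Cdkn2b (3.92 ± 0.29), both inhibitors of cyclin-dependent kinases, were among the largest changes.

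Glycolysis, sterol synthesis and ribosome biogenesis lists were higher in the tumours. Among 25 glycolysis and hypoxia genes, over all genes 15 rose and 1 fell, 17 and 1 adjusted over the list alone. Their median was 1.89, or 1.85 with dim members at their bound (camera adjusted p = 9.99e-07, adjusted p = 0.234 with an estimated correlation). The largest changes were in Slc16a3 (6.53 ± 0.34), a lactate transporter, and Car9 (4.48 ± 0.72), a carbonic anhydrase of hypoxic cells that was well above background on 1 of 2 parotid arrays. For 25 sterol and fatty acid synthesis genes, over all genes 16 rose and 2 fell, 18 and 2 adjusted over the list alone. Their median was 1.39 (camera adjusted p = 0.000284, adjusted p = 0.234 with an estimated correlation). Sqle (3.07 ± 0.26), an enzyme of cholesterol synthesis, was among the largest changes. For 25 ribosome biogenesis genes, over all genes 12 rose and 0 fell, 14 and 0 adjusted over the list alone. Their median was 0.80 (camera adjusted p = 0.000156, adjusted p = 0.234 with an estimated correlation). Mybbp1a (1.52 ± 0.26) and Gar1 (1.39 ± 0.23) were among the largest changes. The ER folding, ATF4 and lysosome lists were lower. For 22 genes of ER folding and the unfolded protein response, over all genes 0 rose and 8 fell, 0 and 8 adjusted over the list alone. Their median was −0.95 (camera adjusted p = 0.00563, adjusted p = 0.769 with an estimated correlation). Herpud1 (−3.51 ± 0.37) and Dnajb9 (−2.20 ± 0.42) were among the largest changes. In the ATF4 list of amino acid and one-carbon genes (18 tested), over all genes 0 rose and 11 fell, 1 and 12 adjusted over the list alone. Their median was −1.55 (camera adjusted p = 0.00433, adjusted p = 0.769 with an estimated correlation). Chac1 (−4.57 ± 0.73) fell, and Slc7a11, the cystine transporter, fell by at least 9.09-fold. For 21 lysosome and autophagy genes, over all genes 0 rose and 5 fell, 0 and 5 adjusted over the list alone. Their median was −0.61 (camera adjusted p = 0.0301, adjusted p = 0.769 with an estimated correlation). Map1lc3a (−2.55 ± 0.26) and Ctsl (−1.41 ± 0.34) were among the largest changes. The lysosome call was lost with slide as a fixed block, without untreated tumour replicate 1 and without parotid replicate 2, and the ER call without parotid replicate 2.

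Transcripts of lymphocytes, fat and muscle were lower in the tumours than in the parotid glands. For 11 B and plasma cell genes, over all genes 0 rose and 7 fell, 0 and 10 adjusted over the list alone. Their median was −6.34, or −5.81 with dim members at their bound (camera adjusted p = 4.34e-05, adjusted p = 0.473 with an estimated correlation). Jchain (−9.08 ± 0.47), the joining chain of secreted antibodies, and Pou2af1 (−8.57 ± 0.67) were among the largest changes. For 12 T cell genes, over all genes 0 rose and 8 fell, 0 and 8 adjusted over the list alone. Their median was −5.05, or −3.87 with dim members at their bound (camera adjusted p = 0.00433, adjusted p = 0.619 with an estimated correlation). Cd3d (at least 112-fold lower) and Cd3g (at least 51.8-fold lower), chains of the T cell receptor complex, were among the largest changes. Their parotid standard deviations were 4.21 and 4.47, so the parotid arrays differed widely. The T cell list stood at 5.64 in parotid replicate 1 and 2.29 in replicate 2 relative to untreated tumour, and the B and plasma cell list at 7.41 and 4.44. The T cell median was −2.81 without parotid replicate 1 and −6.13 without replicate 2, and 3 and 2 T cell genes were lower without untreated tumour replicate 1 and 2. Adipocyte genes (10 tested) included Cfd (−9.45 ± 1.88) and Adipoq (−8.23 ± 1.22), and over all genes 1 rose and 5 fell, 1 and 5 adjusted over the list alone. Their median was −4.46, or −3.34 with dim members at their bound (camera adjusted p = 0.0301, adjusted p = 0.769 with an estimated correlation). In the skeletal muscle list of 14, over all genes 0 rose and 3 fell, 0 and 3 adjusted over the list alone. Their median was −4.31, or −3.03 with dim members at their bound (camera adjusted p = 0.0140, adjusted p = 0.769 with an estimated correlation). Ckm (at least 31.5-fold lower) and Myh2 (at least 14.4-fold lower) were among the largest changes. The muscle genes were high in parotid replicate 2 alone among the parotid arrays, with a list level of 6.06 relative to untreated tumour against 1.44 in replicate 1. The adipocyte and muscle calls were lost without parotid replicate 2, and the muscle median was then −1.06. Pou2af1, Cfd and Adipoq were well above background on 1 of 2 tumour arrays, where Cfd had a standard deviation of 4.39 and Adipoq of 2.68, and Myh2 on 1 of 2 parotid arrays.

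The other lists did not pass camera against parotid. Among gland cell lists these were duct epithelium (median 0.42, 7 higher and 6 lower, 7 and 6 adjusted over the list alone) and basal and myoepithelial (median −0.97, 1 higher and 5 lower, 1 and 5 adjusted over the list alone). Among signalling lists they were PI3K-AKT-mTOR components (median −0.16, 3 higher and 5 lower, 3 and 5 adjusted over the list alone), FOXO targets (median −0.62, 2 higher and 6 lower, 3 and 7 adjusted over the list alone) and immediate early and stress (median 0.25, 3 higher and 2 lower, 3 and 2 adjusted over the list alone). Mitochondrial respiration (median −0.18, 1 higher and 3 lower, 0 and 2 adjusted over the list alone) and interferon response (median −0.53, 0 higher and 6 lower, 0 and 5 adjusted over the list alone) did not pass. Among immune lists, macrophage (median −0.25, 3 higher and 3 lower, 3 and 3 adjusted over the list alone) and neutrophil (median 2.30, 2 higher and 0 lower, 2 and 0 adjusted over the list alone) did not pass. Among stromal lists, endothelial (median −0.73, 0 higher and 4 lower, 0 and 3 adjusted over the list alone), fibroblast and matrix (median −0.34, 0 higher and 5 lower, 0 and 5 adjusted over the list alone) and nerve and Schwann cell (median −0.22, 1 higher and 3 lower, 1 and 3 adjusted over the list alone) did not pass, and neither did sex chromosome genes (median −0.99, 0 higher and 0 lower, 0 and 0 adjusted over the list alone).

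Single members of those lists changed with duct and stromal cell types. Slc9a3 (at least 95.9-fold higher), a sodium-proton exchanger, rose, and Ascl3 (at least 45.2-fold lower), a transcription factor of duct cells, fell. The smooth muscle transcripts Myh11 (−4.77 ± 0.43) and Cnn1 (−4.16 ± 0.86) fell, as did Cd163 (−6.10 ± 0.54), a macrophage scavenger receptor, Ccr2 (−1.57 ± 0.44), Vwf (−2.63 ± 0.66), Lum (−5.396 ± 0.78) and Pdgfra (at least 29.7-fold lower). Tek, an endothelial receptor, passed the test but was dim in both groups, so no fold is given. Rises were seen in S100a8 (5.35 ± 0.92) and S100a9 (4.02 ± 0.93), which neutrophils express, in Atf3 (3.41 ± 0.79) and in Fos (at least 3.34-fold higher). Falls were also seen in Sesn1 (−3.101 ± 0.21), Klf2 (−2.01 ± 0.47), Ppargc1a (−2.63 ± 0.26), Gbp2 (−2.40 ± 0.51) and Irf7 (−1.40 ± 0.43). Probes of a gene disagreed for Ncam1 (−3.22 to 3.54) and Tfam (−2.75 to 1.29), whose reported values were 3.54 ± 0.36 and −2.75 ± 0.43. They were far apart for Prss56 (7.59 to 10.09), Slc9a3 (2.60 to 7.18), Klf2 (−3.03 to −2.01) and Myh2 (−5.92 to −3.03). Cd163 was well above background on 1 of 2 tumour arrays and S100a8 on 1 of 2 parotid arrays.

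Among PI3K pathway members, Fkbp1a (2.50 ± 0.30, adjusted p = 0.00177), which encodes the protein that binds rapamycin, was higher, and Eif4ebp1 (−2.72 ± 0.41, adjusted p = 0.00370), a repressor of translation that mTOR inactivates, was lower. Of the genes fixed in advance, Ctnnb1 (1.16 ± 0.23, adjusted p = 0.0108), which encodes beta-catenin, rose. For Apc the reported probe gave 1.15 ± 0.31 (adjusted p = 0.0288), but its probes ranged from −0.49 to 1.58. Akt1 (0.57 ± 0.22, adjusted p = 0.0899), Akt2 (−0.03 ± 0.28, adjusted p = 0.935) and Mtor (0.55 ± 0.26, adjusted p = 0.145) did not pass, but probes differed in sign for Akt1 (−0.58 to 0.57) and Akt2 (−0.03 to 0.36). The data do not say which probes would detect an introduced AKT gene.

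The comparison of day 14 with untreated tumour asked how the tumours changed under the longer rapamycin treatment, with n = 2 against 2. At day 14 the secretory transcripts of the gland were high and transcripts of cell division were low. Klk1b4 (15.87 ± 0.84, adjusted p = 0.000179) and Prol1 (13.37 ± 0.99, adjusted p = 0.000369), a salivary mucin named Muc10 in the files, rose. Ccnb1 (−5.65 ± 0.40, adjusted p = 0.000333), the cyclin of mitosis, and Sp5 (−6.92 ± 0.40, adjusted p = 0.000213), the Wnt target, fell. Klk1b4 and Prol1 were well above background on 1 of 2 untreated tumour arrays, as were Klk1b26, Cd163, Pou2af1 and Cfd below. Cftr was so only by an unreported probe, so no size is given. Ccnb1 and Car9 were so on 1 of 2 day 14 arrays.

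The largest rises were in kallikreins and skeletal muscle myosins: Klk1b24 (at least 30466-fold higher), Klk1b9 (at least 25590.5-fold higher), Klk1b27 (at least 15335-fold higher), Klk1b16 (at least 14843-fold higher), Klk1b26 (15.86 ± 0.88), Myh8 (at least 33432-fold higher) and Myh4 (at least 15618-fold higher). The kallikreins, Dcpp and Prb genes are families of close relatives whose probes can share signal, so their separate values are uncertain. The largest falls were in Bex1 (at least 92.5-fold lower), Bhmt (at least 71.4-fold lower) and Dmgdh (at least 87.2-fold lower), enzymes of betaine and glycine metabolism in the latter pair, and in Crct1 (at least 49.2-fold lower), Lyg1 (at least 47.9-fold lower), Ano9 (at least 47.0-fold lower), Gsdma (at least 37.0-fold lower) and Prss56 (−7.26 ± 0.50). limma called 7809 of 16362 genes, 3971 higher and 3838 lower, and 6862 by at least 2-fold. Untreated tumour was dim for 670 of them, day 14 for 664 and both for 138. The 138 and 83 more had no fold. The count was 4484 without untreated tumour replicate 1, 3999 without replicate 2, 3736 without day 14 replicate 1 and 4043 without day 14 replicate 2. It was 6828 with slide as a fixed block and 9171 within slide 1.

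Both gland lists rose at day 14. Of 22 acinar secretory genes, over all genes 19 rose and 1 fell, 19 and 1 adjusted over the list alone. Their median was 7.38, or 6.83 with dim members at their bound (camera adjusted p = 1.24e-07, adjusted p = 0.326 with an estimated correlation). Dcpp2 (at least 15670.5-fold higher) was among the largest changes of the list, and Ano1 was the member that fell. Of the 18 granular duct and mucous genes, over all genes 18 rose and 0 fell, 18 and 0 adjusted over the list alone. Their median was 14.62, or 13.82 with dim members at their bound (camera adjusted p = 1.70e-13, adjusted p = 0.326 with an estimated correlation). Proliferation genes (33 tested) fell together: over all genes 0 rose and 33 fell, 0 and 33 adjusted over the list alone. Their median was −4.40, or −4.21 with dim members at their bound (camera adjusted p = 3.30e-14, adjusted p = 0.417 with an estimated correlation). Cdk1 (at least 48.9-fold lower) was among the largest falls of that list, though its probes ranged from −6.26 to −0.99. Across 21 Wnt targets, over all genes 1 rose and 15 fell, 1 and 15 adjusted over the list alone. Their median was −3.12, or −3.08 with dim members at their bound (camera adjusted p = 8.90e-07, adjusted p = 0.152 with an estimated correlation). The Wnt inhibitor Notum (at least 40.6-fold lower) was among those lower. Among the cell cycle inhibitors and p53 targets, over all genes 0 rose and 7 fell, 0 and 7 adjusted over the list alone. Their median was −0.65 (camera adjusted p = 0.0277, adjusted p = 0.417 with an estimated correlation). Cdkn1a (−5.01 ± 0.27) and Cdkn2a (at least 3.28-fold lower) were among the largest changes. The call for cell cycle inhibitors was lost without parotid replicate 1, without parotid replicate 2 and with quantile normalization. Without day 14 replicate 1 the counts higher and lower were 13 and 0 acinar, 17 and 0 granular duct, 0 and 31 proliferation and 0 and 13 Wnt genes. Without day 14 replicate 2 they were 12 and 0, 17 and 0, 0 and 32, and 0 and 12. Within slide 1 they were 17 and 1, 17 and 0, 0 and 33, and 1 and 16.

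**Figure D1:**
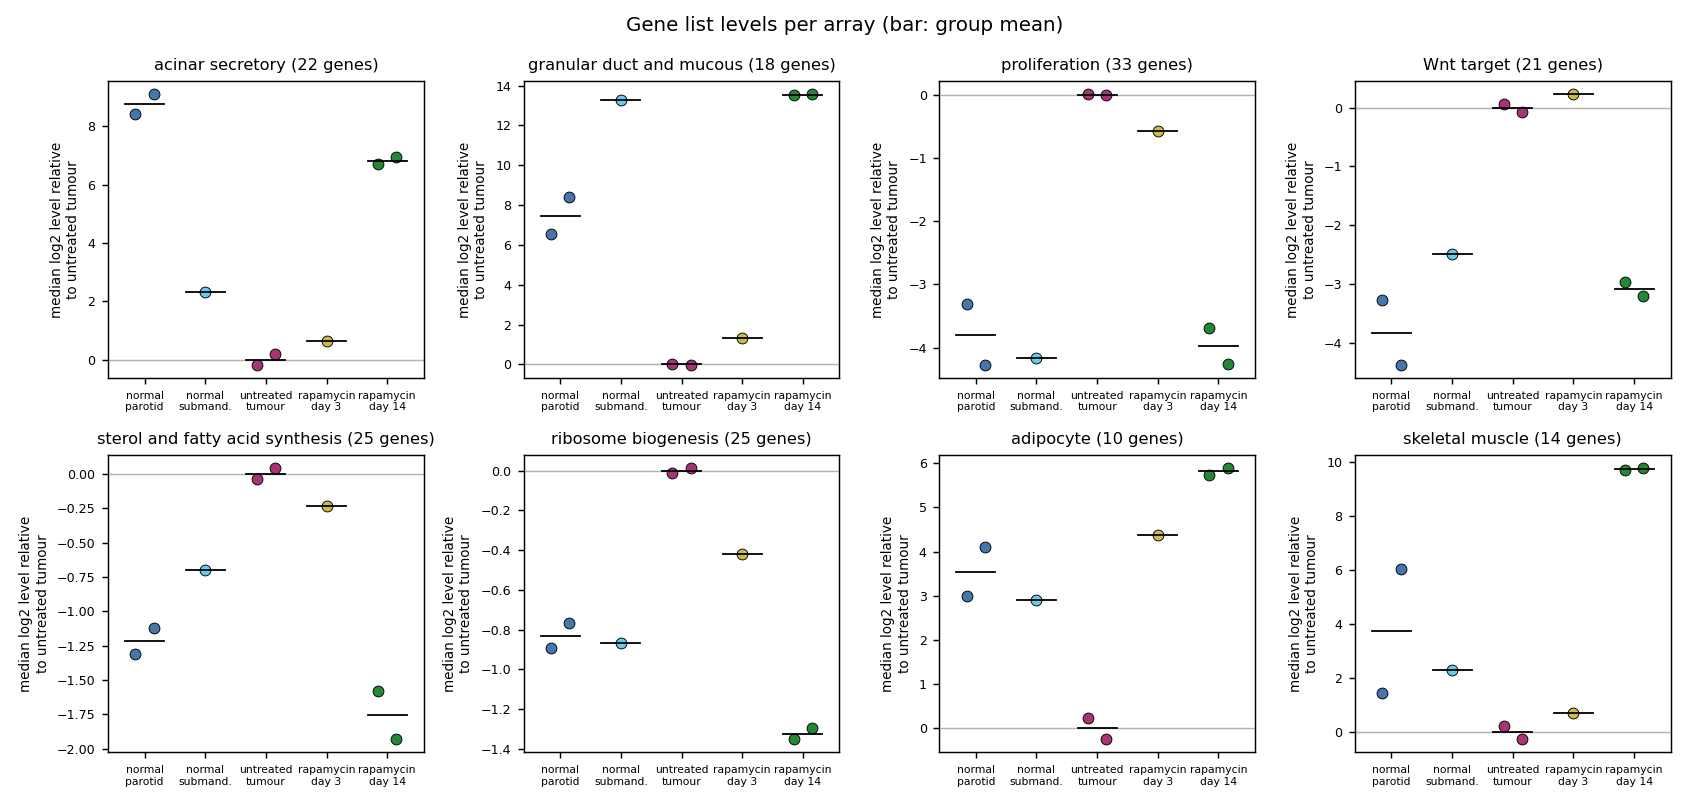
Median log2 signal of 8 gene lists on each array, relative to untreated tumour (points, arrays by group; bars, group means). Granular duct genes stood at 13.51 and 13.56 in the day 14 arrays and at 1.35 at day 3, and proliferation genes at −3.69 and −4.26 against −0.58.

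Ribosome biogenesis, sterol synthesis and glycolysis lists fell at day 14. Of 25 ribosome biogenesis genes, over all genes 0 rose and 23 fell, 0 and 24 adjusted over the list alone. Their median was −1.32 (camera adjusted p = 3.80e-08, adjusted p = 0.152 with an estimated correlation). Gar1 (−3.42 ± 0.23) and Nop14 (−2.26 ± 0.31) were among the largest changes. In sterol and fatty acid synthesis (25 tested), over all genes 1 rose and 19 fell, 1 and 19 adjusted over the list alone. Their median was −1.64 (camera adjusted p = 6.34e-06, adjusted p = 0.152 with an estimated correlation). Fdps (−4.11 ± 0.41) and Cyp51 (at least 11.1-fold lower) were among the largest changes. In glycolysis and hypoxia (25 tested), over all genes 2 rose and 14 fell, 3 and 14 adjusted over the list alone. Their median was −1.31 (camera adjusted p = 0.00182, adjusted p = 0.326 with an estimated correlation). Car9 (−5.10 ± 0.72) and Eno1 (−4.69 ± 0.25) were among the largest changes. FOXO targets (17 tested), which AKT represses, rose: over all genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone. Their median was 0.74 (camera adjusted p = 0.00649, adjusted p = 0.326 with an estimated correlation). Trim63 (at least 65.99-fold higher), which muscle expresses, and Pdk4 (2.78 ± 0.36) led them. ER folding genes rose: over all genes 7 rose and 0 fell, 7 and 0 adjusted over the list alone. Their median was 0.88 (camera adjusted p = 0.00874, adjusted p = 0.719 with an estimated correlation). Herpud1 (3.06 ± 0.37) and Dnajc3 (1.88 ± 0.29) were among the largest changes. Without day 14 replicate 1 or 2, the sterol genes were 1 higher and 13 lower or 0 and 13, and within slide 1 they were 1 and 19.

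Transcripts of fat, muscle, lymphocytes, vessels and myoepithelium were also higher at day 14. In the skeletal muscle list, over all genes 13 rose and 0 fell, 13 and 0 adjusted over the list alone. Their median was 11.12, or 9.79 with dim members at their bound (camera adjusted p = 1.28e-05, adjusted p = 0.436 with an estimated correlation). Tnnc2 (13.65 ± 2.83) was among the largest changes. In the adipocyte list, over all genes 10 rose and 0 fell, 10 and 0 adjusted over the list alone. Their median was 7.45, or 5.99 with dim members at their bound (camera adjusted p = 1.29e-05, adjusted p = 0.436 with an estimated correlation). Cfd (9.68 ± 1.88) and Plin1 (at least 276-fold higher) were among the largest changes. In the B and plasma cell list, over all genes 10 rose and 0 fell, 11 and 0 adjusted over the list alone. Their median was 7.997, or 6.67 with dim members at their bound (camera adjusted p = 1.61e-05, adjusted p = 0.417 with an estimated correlation). Pou2af1 (9.50 ± 0.67) was among the largest changes. In the T cell list, over all genes 8 rose and 0 fell, 8 and 0 adjusted over the list alone. Their median was 4.53, or 3.49 with dim members at their bound (camera adjusted p = 0.00422, adjusted p = 0.436 with an estimated correlation). Cd3d (at least 188-fold higher) and Cd8a (at least 73.7-fold higher) were among the largest changes. In the endothelial list, over all genes 7 rose and 0 fell, 7 and 0 adjusted over the list alone. Their median was 1.44 (camera adjusted p = 0.00271, adjusted p = 0.436 with an estimated correlation). Vwf (4.38 ± 0.66) and Tek (at least 8.32-fold higher) were among the largest changes. In the basal and myoepithelial list, over all genes 7 rose and 1 fell, 7 and 1 adjusted over the list alone. Their median was 3.42 (camera adjusted p = 0.00390, adjusted p = 0.603 with an estimated correlation). Myh11 (6.66 ± 0.43) and Cnn1 (6.52 ± 0.86) were among the largest changes. Macrophage genes fell on balance: over all genes 3 rose and 8 fell, 3 and 9 adjusted over the list alone. Their median was −1.15, or −0.65 with dim members at their bound (camera adjusted p = 0.0321, adjusted p = 0.436 with an estimated correlation). Cd163 (5.25 ± 0.54) rose there and Cd68 (−2.95 ± 0.28) fell. The macrophage call was lost without untreated tumour replicate 2 and with quantile normalization. Without either day 14 array 8 muscle and 6 B cell genes were higher.

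Further lists were not called at day 14 against untreated tumour. They were duct epithelium (median −0.22, 8 higher and 6 lower, 8 and 6 adjusted over the list alone), PI3K-AKT-mTOR components (median 0.20, 5 higher and 5 lower, 5 and 5 adjusted over the list alone) and ATF4 (median 0.78, 6 higher and 2 lower, 6 and 2 adjusted over the list alone). Lysosome (median 0.09, 4 higher and 2 lower, 4 and 2 adjusted over the list alone), mitochondrial respiration (median 0.12, 5 higher and 1 lower, 3 and 0 adjusted over the list alone) and interferon response (median −0.31, 2 higher and 2 lower, 1 and 2 adjusted over the list alone) were not called. Nor were neutrophil (median −4.48, 0 higher and 2 lower, 0 and 2 adjusted over the list alone), fibroblast (median −0.38, 5 higher and 2 lower, 3 and 2 adjusted over the list alone) and nerve genes (median 0.64, 3 higher and 1 lower, 3 and 1 adjusted over the list alone). Immediate early (median 0.00, 0 higher and 1 lower, 0 and 0 adjusted over the list alone) and sex chromosome genes (median 3.88, 0 higher and 0 lower, 0 and 0 adjusted over the list alone) were not called either. The duct list had a negative median but a positive mean (1.12), and the fibroblast and immediate early lists also differed in sign between median, mean or camera direction. Single members that rose were Ascl3 (at least 206-fold higher), the chloride channel Cftr and Deptor (2.09 ± 0.30), an inhibitor of mTOR. Rises were also seen in Chac1 (3.76 ± 0.73), Atf5 (2.35 ± 0.59), Map1lc3a (2.26 ± 0.26), Ppargc1a (3.45 ± 0.26), Gbp2 (1.71 ± 0.51), Pdgfra (at least 24.6-fold higher), Dcn (4.04 ± 0.47) and S100b (2.24 ± 0.29). Single members that fell were Fkbp1a (−3.50 ± 0.30), Oas1a (−2.01 ± 0.31), S100a8 (at least 34.2-fold lower), S100a9 (−4.48 ± 0.93) and Atf3 (−3.39 ± 0.79). Tfam was reported at 2.35 ± 0.43, with probes from −1.17 to 2.35.

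Among the fixed genes at day 14, Ctnnb1 (−1.28 ± 0.23, adjusted p = 0.00618) and Akt2 (−0.84 ± 0.28, adjusted p = 0.0478) were lower than in untreated tumour. Apc was reported at −0.95 ± 0.31 (adjusted p = 0.0438), with probes from −1.32 to 1.22. Akt1 (−0.63 ± 0.22, adjusted p = 0.0583) and Mtor (−0.31 ± 0.26, adjusted p = 0.367) did not pass with their reported probes. Probes of a gene were far apart for Mtor (−1.90 to −0.31) and Ctnnb1 (−2.48 to −0.33). All of these were lower, but the size depends on the probe. Those of Akt1 differed in sign (−0.63 to 0.07), so its direction depends on the probe. Among the genes above they were far apart for Klk1b26 (15.86 to 17.63), Gsdma (−7.22 to −5.92) and Fdps (−4.11 to −1.12).

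**Figure D2:**
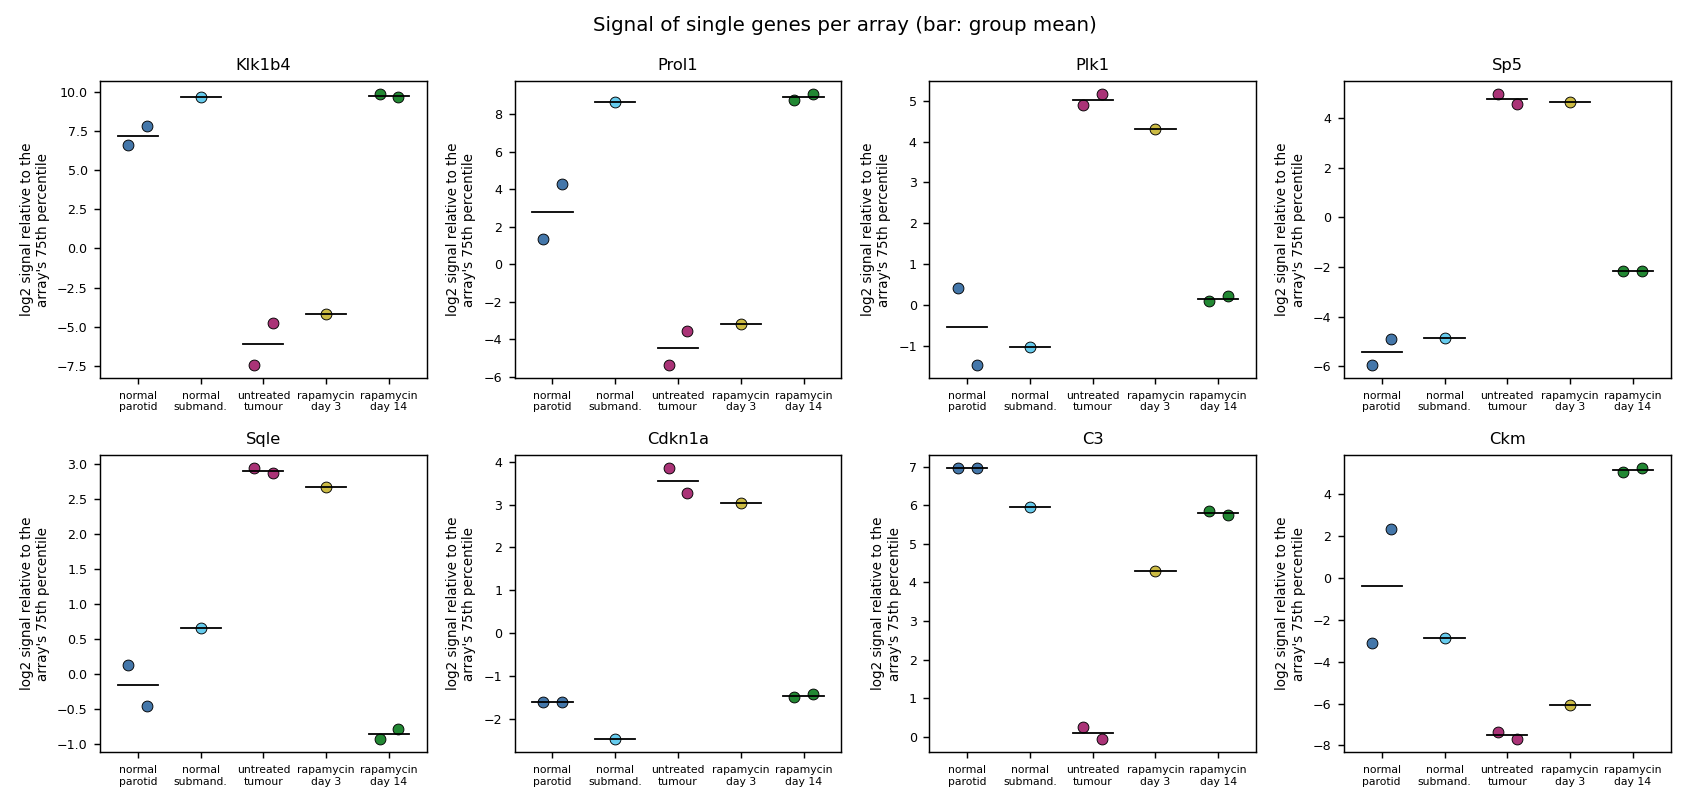
Log2 signal of 8 genes on each array relative to the array's 75th percentile (points, arrays by group; bars, group means). C3 was at 0.24 and −0.05 in untreated tumour and 4.31 at day 3.

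The genes that distinguished tumour from parotid moved back at day 14. Of the 3062 genes higher in untreated tumour, 2375 (77.6%) were lower at day 14 than in untreated tumour and 41 were higher still. Independent lists would share 718 of the former. Simulated unchanged groups that share the untreated tumour arrays shared a mean of 0 called genes, or 1564 in same-sized lists by rank. Of the 3327 genes lower in tumour, 2569 (77.2%) rose at day 14 and 11 fell further, against 807, 0 and 1699 in that order. Shared arrays may add a part, which ranks of unchanged genes cannot size. Over genes, which are not independent replicates, the tumour and day 14 log2 differences correlated at r = −0.85. Both share the untreated tumour arrays, and 200 simulations of unchanged groups that share them gave a mean r of −0.50, from −0.526 to −0.463. The covariance was −4.03 against −0.125 in the simulations. Differences between single arrays that share none gave r from −0.803 to −0.750 over 8 pairs, and within slide 1 r was −0.806.

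**Figure D3:**
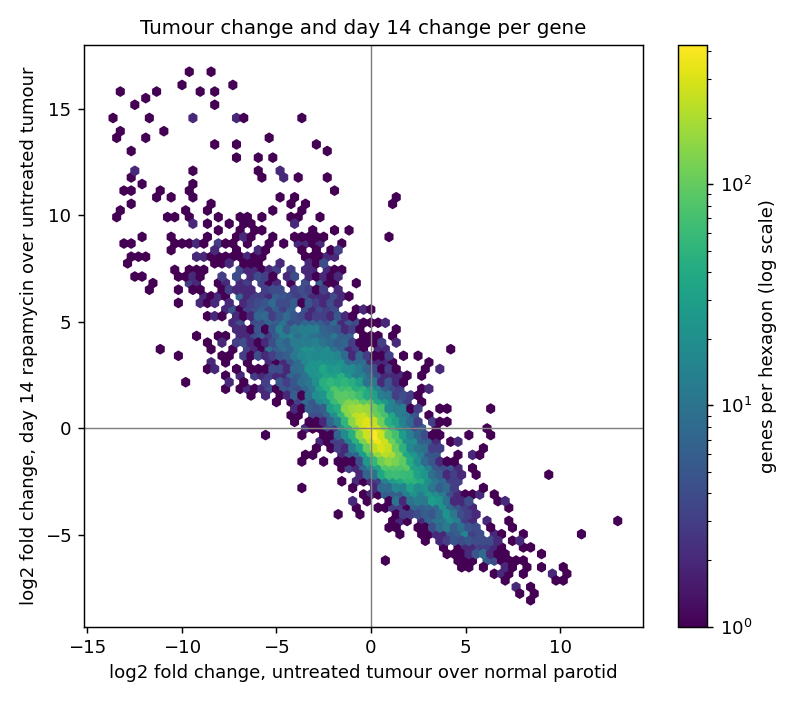
Log2 difference of untreated tumour from parotid (x axis) against log2 difference of day 14 from untreated tumour (y axis) for 16362 genes, shaded by the number of genes. The differences correlated at r = −0.85. Simulations of unchanged groups that share the untreated tumour arrays gave a mean r of −0.50 and a covariance of −0.125, against a covariance of −4.03 here.

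Day 3 was compared with untreated tumour for the early change, n = 1 against 2. C3, a complement protein, was higher at day 3 (4.21 ± 0.25, adjusted p = 0.0272), with its probe at chromosome 17, 56889328 to 56889387. Adipocyte genes, 10 tested, were higher: median 5.50, or 4.37 with dim members at their bound, with 0 higher over all genes and 6 higher adjusted over the list alone (camera adjusted p = 3.50e-09, adjusted p = 0.542 with an estimated correlation). Ribosome biogenesis was lower as a group (median −0.42, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 4.17e-08, adjusted p = 0.384 with an estimated correlation). For proliferation genes the values were lower in this fit (median −0.58, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 1.92e-06, adjusted p = 0.761 with an estimated correlation). Glycolysis genes were lower (median −0.48, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 7.82e-06, adjusted p = 0.384 with an estimated correlation). Sterol synthesis genes were lower (median −0.24, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.00618, adjusted p = 0.384 with an estimated correlation). Mitochondrial respiration genes were lower too (median −0.23, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.00561, adjusted p = 0.822 with an estimated correlation). This comparison lies wholly between slides, and a slide term rests on the parotid and day 14 pairs, so sample differences enter it. With slide as a fixed block C3 was at 4.27 ± 0.34 (adjusted p = 0.575), so its size held but its call was lost, with 2 residual degrees of freedom left in place of 3. In that fit the proliferation median was 0.0302 and its call was lost, so that fall is uncertain. The medians were then −0.51 for ribosome biogenesis, −0.68 for glycolysis, −0.25 for sterol synthesis, −0.56 for mitochondrial respiration and 4.91 for adipocyte genes, whose calls held.

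Basal and myoepithelial genes were higher as a group at day 3 (median 1.70, or 1.68 with dim members at their bound, 0 higher and 0 lower, 3 and 0 adjusted over the list alone, camera adjusted p = 1.40e-05, adjusted p = 0.718 with an estimated correlation). Endothelial genes were higher (median 0.75, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.00499, adjusted p = 0.755 with an estimated correlation). Nerve and Schwann cell genes were higher (median 0.68, 0 higher and 0 lower, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.493 with an estimated correlation). Fibroblast genes were higher (median 0.89, or 0.86 with dim members at their bound, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.841 with an estimated correlation). Granular duct genes passed camera (median 1.44, or 0.00 with dim members at their bound, 0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 7.82e-06, adjusted p = 0.633 with an estimated correlation), but 10 of the 18 members were dim in a group, so no rise is stated. The mitochondrial, endothelial and nerve calls were lost without untreated tumour replicate 2, and the fibroblast call without parotid replicate 1 and with slide as a fixed block. The fibroblast median was −0.22 without untreated tumour replicate 2, and the granular duct median was −0.0918 with normexp background correction. Acinar genes (median 0.52, 0 higher and 0 lower, 0 and 0 adjusted over the list alone), Wnt targets (median 0.23, 0 higher and 0 lower, 0 and 0 adjusted over the list alone) and skeletal muscle genes (median 0.72, 0 higher and 0 lower, 0 and 0 adjusted over the list alone) were not called. In limma 1 gene, C3, passed over all genes, and 1436 had an unadjusted p under 0.05. The count was 0 without either untreated tumour or either day 14 array, 286 without parotid replicate 1 and 288 without parotid replicate 2. Both parotid arrays enter only through the pooled spread. In simulated data with this design, 76% of genes shifted by 4 on the log2 scale and 12% of those shifted by 2 were called. Of the unshifted genes 1 was called, as many as in the data. Akt1 (−0.24 ± 0.27, adjusted p = 0.904), Akt2 (−0.48 ± 0.34, adjusted p = 0.789), Apc (−0.15 ± 0.38, adjusted p = 0.958), Ctnnb1 (−0.07 ± 0.28, adjusted p = 0.975) and Mtor (−0.01 ± 0.32, adjusted p = 0.998) did not pass. Probes differed in sign for Akt1 (−0.24 to 0.57), Apc (−0.15 to 0.13) and Ctnnb1 (−0.55 to 0.32).

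Day 14 was compared with day 3 to ask how the samples of the later and earlier time differed, with n = 2 against 1. Gland transcripts were higher and proliferation transcripts lower at day 14 than at day 3. Klk1b24 (at least 11963-fold higher), Klk1b27 (at least 6021-fold higher) and Dcpp2 (at least 6153-fold higher) rose, with the muscle myosins Myh8 (at least 13128-fold higher) and Myh4 (at least 6133-fold higher). Cdkn1a (−4.48 ± 0.34, adjusted p = 0.00165), Sqle (−3.53 ± 0.32, adjusted p = 0.00212) and the Wnt target Notum (at least 47.5-fold lower, adjusted p = 0.00272) fell. Further falls were in Bhmt (at least 96.3-fold lower), Msx2 (at least 90.8-fold lower), Sprr1a (at least 88.3-fold lower) and Lyg1 (at least 39.7-fold lower). limma called 3724 genes, 1788 higher and 1936 lower. The count was 834 without day 14 replicate 1, 769 without day 14 replicate 2, 2414 and 2427 without untreated tumour replicate 1 and 2, 7463 and 7468 without parotid replicate 1 and 2, and 2825 with slide as a fixed block.

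Between day 3 and day 14, within the granular duct list, over all genes 17 rose and 0 fell, 18 and 0 adjusted over the list alone. Their median was 13.19, or 12.19 with dim members at their bound (camera adjusted p = 1.28e-17, adjusted p = 0.269 with an estimated correlation). Acinar genes followed: over all genes 13 rose and 0 fell, 17 and 0 adjusted over the list alone. Their median was 7.04, or 6.45 with dim members at their bound (camera adjusted p = 1.68e-09, adjusted p = 0.269 with an estimated correlation). For proliferation, over all genes 0 rose and 31 fell, 0 and 33 adjusted over the list alone. Their median was −3.77, or −3.49 with dim members at their bound (camera adjusted p = 2.12e-15, adjusted p = 0.364 with an estimated correlation). For Wnt targets, over all genes 0 rose and 16 fell, 0 and 16 adjusted over the list alone. Their median was −2.94, or −2.82 with dim members at their bound (camera adjusted p = 5.77e-09, adjusted p = 0.160 with an estimated correlation). For sterol synthesis, over all genes 1 rose and 13 fell, 1 and 16 adjusted over the list alone. Their median was −1.37, or −1.36 with dim members at their bound (camera adjusted p = 2.65e-06, adjusted p = 0.160 with an estimated correlation). For ribosome biogenesis, over all genes 0 rose and 9 fell, 0 and 15 adjusted over the list alone. Their median was −0.85 (camera adjusted p = 4.15e-06, adjusted p = 0.254 with an estimated correlation). For skeletal muscle, over all genes 12 rose and 0 fell, 13 and 0 adjusted over the list alone. Their median was 10.19, or 8.47 with dim members at their bound (camera adjusted p = 1.09e-06, adjusted p = 0.472 with an estimated correlation). For B and plasma cells, over all genes 7 rose and 0 fell, 10 and 0 adjusted over the list alone. Their median was 6.90, or 5.32 with dim members at their bound (camera adjusted p = 3.05e-06, adjusted p = 0.364 with an estimated correlation). For adipocytes, over all genes 4 rose and 0 fell, 4 and 0 adjusted over the list alone. Their median was 1.95 (camera adjusted p = 0.00717, adjusted p = 0.638 with an estimated correlation). These counts depended on the arrays kept. Without day 14 replicate 1 or 2, 11 or 8 proliferation genes were lower, 1 muscle gene was higher and no adipocyte gene was. Without either of these arrays 15 granular duct, 10 acinar and 4 B cell genes were higher, and 11 Wnt, 6 sterol and 1 ribosome biogenesis genes were lower. Without either untreated tumour array 27 proliferation, 15 Wnt, 8 sterol and 3 ribosome biogenesis genes were lower. Without either parotid array these were 33, 18, 20 and 18.

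Other members that rose from day 3 to day 14 were Ascl3 (at least 80.8-fold higher), Myh11 (4.64 ± 0.53), Trim63 (at least 25.9-fold higher), Herpud1 (2.91 ± 0.45), Chac1 (4.37 ± 0.90), Map1lc3a (2.11 ± 0.31) and Ppargc1a (3.40 ± 0.32). Rises among immune, vessel and fat members were in Cd163 (3.09 ± 0.67), Gzma (at least 3.40-fold higher), Pou2af1 (at least 302-fold higher), Tek (at least 3.27-fold higher) and Aqp7. Members that fell were Fkbp1a (−2.95 ± 0.37), Car9 (−3.83 ± 0.89), Gar1 (−2.52 ± 0.28), Oas1a (−1.97 ± 0.38), S100a8 (at least 68.5-fold lower), Col5a2 (at least 12.1-fold lower) and Junb (−1.46 ± 0.22). Car9 was well above background on 1 of 2 day 14 arrays. Aqp7 was so at day 3 only by an unreported probe, so no size is given. Cdk1 was lower by at least 23.8-fold, with probes from −5.22 to 0.41. Ctnnb1 (−1.20 ± 0.28, adjusted p = 0.0299) was lower, and Akt1 (−0.40 ± 0.27, adjusted p = 0.330), Akt2 (−0.36 ± 0.34, adjusted p = 0.473), Apc (−0.79 ± 0.38, adjusted p = 0.173) and Mtor (−0.30 ± 0.32, adjusted p = 0.531) did not pass with their reported probes. Probes were far apart for Mtor (−1.56 to −0.30), Ctnnb1 (−1.94 to −0.65) and Apc (−1.30 to 1.09), so these values depend on the probe.

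The comparison of day 14 with normal parotid asked what still separated treated tumour from that gland, with n = 2 against 2. Transcripts typical of the submandibular gland were higher at day 14, among them Smgc (11.08 ± 1.27, adjusted p = 0.00865), a submandibular gland protein. Lman1l (10.53 ± 0.73, adjusted p = 0.00286) was higher too. Ucp1 (at least 220.5-fold higher, adjusted p = 0.000884), the uncoupling protein of brown fat, was higher. Gar1 (−2.03 ± 0.23, adjusted p = 0.00865), of ribosome biogenesis, and Adgre1 (−2.21 ± 0.30, adjusted p = 0.0131), of macrophages, were lower, as were Gdpd3 (−6.63 ± 0.69), Aspdh (−5.58 ± 0.57), Trim55 (at least 16.4-fold lower) and Vpreb2 (−5.28 ± 0.49). Smgc, Lman1l, Cftr and Tnfrsf19 were well above background on 1 of 2 parotid arrays and Gdpd3 on 1 of 2 day 14 arrays. limma called 1852 genes, 1022 higher and 830 lower. Without day 14 replicate 1 or day 14 replicate 2 the count was 0, without untreated tumour replicate 1 and 2 it was 717 and 731, without parotid replicate 1 it was 5891 and without parotid replicate 2 it was 4117. It was 1509 with slide as a fixed block and 1980 within slide 1, and 4958 genes had an unadjusted p under 0.05.

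Against parotid at day 14, for granular duct genes, over all genes 14 rose and 0 fell, 16 and 0 adjusted over the list alone. Their median was 6.42 (camera adjusted p = 9.69e-14, adjusted p = 0.323 with an estimated correlation). For duct epithelium, over all genes 7 rose and 0 fell, 9 and 0 adjusted over the list alone. Their median was 0.96, or 0.76 with dim members at their bound (camera adjusted p = 0.000222, adjusted p = 0.609 with an estimated correlation). For muscle, over all genes 3 rose and 0 fell, 13 and 0 adjusted over the list alone. Their median was 6.47 (camera adjusted p = 1.93e-06, adjusted p = 0.609 with an estimated correlation). For adipocytes, over all genes 4 rose and 0 fell, 5 and 0 adjusted over the list alone. Their median was 1.93 (camera adjusted p = 0.00152, adjusted p = 0.609 with an estimated correlation). For ribosome biogenesis, over all genes 0 rose and 4 fell, 0 and 9 adjusted over the list alone. Their median was −0.70 (camera adjusted p = 3.96e-06, adjusted p = 0.323 with an estimated correlation). For macrophages, over all genes 1 rose and 10 fell, 1 and 12 adjusted over the list alone. Their median was −1.17 (camera adjusted p = 3.51e-06, adjusted p = 0.323 with an estimated correlation). For acinar genes, over all genes 2 rose and 6 fell, 2 and 8 adjusted over the list alone. Their median was −0.84 (camera adjusted p = 0.00747, adjusted p = 0.609 with an estimated correlation). For sterol synthesis, over all genes 0 rose and 4 fell, 0 and 4 adjusted over the list alone. Their median was −0.56, or −0.51 with dim members at their bound (camera adjusted p = 0.00665, adjusted p = 0.323 with an estimated correlation). Proliferation genes were not called (median −0.17, 0 higher and 0 lower, 0 and 0 adjusted over the list alone). Other members that were higher were Prol1 (6.10 ± 0.99), Cftr (4.20 ± 0.44), Cdh3 (at least 5.90-fold higher), Plk2 (1.49 ± 0.35), Trim63 (at least 19.1-fold higher), Slc16a3 (3.40 ± 0.34), Flt1 (1.76 ± 0.42), Mylpf (5.398 ± 1.09) and S100b (2.82 ± 0.29). Lower were Rps6 (−1.17 ± 0.23), Fdps (−2.37 ± 0.41), Atf4 (−1.47 ± 0.33), Pycr1 (−1.55 ± 0.29) and Oas1a (−2.02 ± 0.31). Probes disagreed for Fn1 (−2.35 to 3.31) and were far apart for Tnfrsf19 (0.05 to 3.77), Lman1l (5.10 to 10.53) and Fdps (−2.37 to −0.30). Of the fixed genes, Akt1 (−0.06 ± 0.22, adjusted p = 0.891), Akt2 (−0.88 ± 0.28, adjusted p = 0.0937), Apc (0.20 ± 0.31, adjusted p = 0.717), Ctnnb1 (−0.12 ± 0.23, adjusted p = 0.785) and Mtor (0.24 ± 0.26, adjusted p = 0.596) did not pass, and probes differed in sign for Ctnnb1 (−0.89 to 1.29) and Mtor (−0.76 to 0.24). Without either day 14 array, no member of these lists was called.

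Untreated tumour was also compared with the single submandibular gland, n = 2 against 1, as the second normal tissue. Kallikreins and other secretory transcripts were again the largest falls, with Klk1b4 (−15.79 ± 1.03, adjusted p = 0.000421), Klk1b24 by at least 20856-fold, Scgb2b26 by at least 23799.9-fold, Crisp3 by at least 12475-fold and Prol1 (−13.10 ± 1.22). Bpifb5 (at least 2258-fold higher), Bpifb9a (at least 1666-fold higher), Dkk2 (at least 219.5-fold higher), Sp5 (at least 211-fold higher) and S100a14 (at least 426-fold higher) were higher, as in the comparison with parotid for all but S100a14, which was not among the genes named there. Klk1b4, Prol1, Cd163 and Cidec were well above background on 1 of 2 tumour arrays. limma called 4817 genes, 2338 higher and 2479 lower. The count was 2467 and 2488 without untreated tumour replicate 1 and 2, 8210 and 8224 without parotid replicate 1 and 2, and 3073 and 3087 without day 14 replicate 1 and 2. It was 2266 with slide as a fixed block.

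Against the submandibular gland, for granular duct genes, over all genes 0 rose and 17 fell, 0 and 17 adjusted over the list alone. Their median was −14.38, or −13.42 with dim members at their bound (camera adjusted p = 7.55e-15, adjusted p = 0.363 with an estimated correlation). For acinar genes, over all genes 2 rose and 12 fell, 2 and 13 adjusted over the list alone. Their median was −2.10, or −1.98 with dim members at their bound (camera adjusted p = 0.000443, adjusted p = 0.434 with an estimated correlation). For proliferation, over all genes 32 rose and 0 fell, 33 and 0 adjusted over the list alone. Their median was 4.97, or 4.16 with dim members at their bound (camera adjusted p = 1.76e-16, adjusted p = 0.425 with an estimated correlation). For Wnt targets, over all genes 15 rose and 0 fell, 15 and 0 adjusted over the list alone. Their median was 3.77, or 2.50 with dim members at their bound (camera adjusted p = 1.66e-07, adjusted p = 0.323 with an estimated correlation). For glycolysis, over all genes 12 rose and 1 fell, 13 and 2 adjusted over the list alone. Their median was 0.98, or 0.97 with dim members at their bound (camera adjusted p = 0.00153, adjusted p = 0.363 with an estimated correlation). For ribosome biogenesis, over all genes 9 rose and 0 fell, 10 and 0 adjusted over the list alone. Their median was 0.87 (camera adjusted p = 0.000131, adjusted p = 0.363 with an estimated correlation). For B and plasma cells, over all genes 0 rose and 6 fell, 0 and 6 adjusted over the list alone. Their median was −4.54, or −3.86 with dim members at their bound (camera adjusted p = 0.000548, adjusted p = 0.506 with an estimated correlation). Other members that were higher were Cdk1 (at least 34.2-fold higher), Cdkn1a (6.02 ± 0.34), Slc16a3 (6.21 ± 0.41), Mvd (2.46 ± 0.30), S100a9 (at least 155-fold higher) and Atf3 (3.28 ± 0.96). Nolc1 had probes from −0.996 to 1.30 and Cdk1 from 0.58 to 6.70, so the fold of Cdk1 depends on the probe. Lower were Ascl3 (at least 465-fold lower), Myh11 (−7.46 ± 0.53), Deptor (−2.98 ± 0.37), Txnip (−2.09 ± 0.30), Herpud1 (−3.60 ± 0.45), Chac1 (−3.05 ± 0.90), Map1lc3a (−3.03 ± 0.31), Ppargc1a (−2.91 ± 0.32) and Oasl2 (−3.42 ± 0.32). Of immune and stromal members, lower ones were Cd163 (−3.07 ± 0.67), Gzma (at least 24.8-fold lower), Jchain (−8.89 ± 0.57), Vwf (−3.16 ± 0.81), Pdgfra (at least 40.1-fold lower) and Cidec (−5.94 ± 1.58). Akt1 (−0.22 ± 0.27, adjusted p = 0.583), Akt2 (0.10 ± 0.34, adjusted p = 0.852), Apc (1.03 ± 0.38, adjusted p = 0.0866), Ctnnb1 (0.57 ± 0.28, adjusted p = 0.182) and Mtor (−0.34 ± 0.32, adjusted p = 0.461) did not pass with their reported probes. Probes differed in sign for Mtor (−0.34 to 1.76), Akt1 (−0.22 to 0.56) and Akt2 (−0.18 to 0.10) and were far apart for Ctnnb1 (0.57 to 3.08).

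The normal glands were compared with each other, n = 1 submandibular against 2 parotid, as a reference for gland identity. Smgc was higher in the submandibular gland (11.27 ± 1.56, adjusted p = 0.0240), although its probes ranged from 0.53 to 11.27 and it was well above background on 1 of 2 parotid arrays. Spata31d1d (at least 105-fold higher) and the sodium channel subunit Scnn1b (4.07 ± 0.55) were higher too. Dcpp1 was lower by at least 6305-fold, Prb1 by at least 2748-fold, Scgb2b20 by at least 2087-fold and Cldn22 by at least 907-fold. Other members called were Nkd1 (2.88 ± 0.29), Gadd45a (2.66 ± 0.34), Hk1 (1.87 ± 0.28), Oasl2 (2.06 ± 0.32) and Ncam1 (2.64 ± 0.44), all higher, Rrm2, lower by at least 5.34-fold, and Fn1, with probes from −2.13 to 6.14. Neither Akt1, Akt2, Apc, Ctnnb1 nor Mtor passed with its reported probe, and probes differed in sign for Akt1 (−1.14 to 0.78), Akt2 (−0.13 to 0.53), Apc (−1.66 to 0.59), Ctnnb1 (−1.46 to 0.86) and Mtor (−0.62 to 0.89). Those of Dcpp1 ranged from −14.69 to −12.13 and those of Ncam1 from 0.61 to 2.64. For granular duct genes, over all genes 11 rose and 0 fell, 14 and 1 adjusted over the list alone. Their median was 5.52 (camera adjusted p = 1.58e-15, adjusted p = 0.480 with an estimated correlation). For duct epithelium, over all genes 4 rose and 0 fell, 13 and 0 adjusted over the list alone. Their median was 1.75 (camera adjusted p = 4.19e-09, adjusted p = 0.524 with an estimated correlation). For acinar genes, over all genes 0 rose and 8 fell, 1 and 10 adjusted over the list alone. Their median was −0.72 (camera adjusted p = 5.07e-06, adjusted p = 0.524 with an estimated correlation). limma called 384 genes, 223 higher and 161 lower. The count was 9 without either day 14 array, 183 and 187 without untreated tumour replicate 1 and 2, 1936 without parotid replicate 1, 3385 without parotid replicate 2 and 118 with slide as a fixed block.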

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

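The test of parotid as the sole gland tissue was planned before its result was seen, and the tests of sex, of dilution, of an almost wholly normal sample and both muscle tests were chosen only after the results were seen. The day 14 and day 3 samples differed, by limma's test, in 3724 genes. Both changes share the untreated tumour baseline, so this test is also that of their difference. It does not show a drug effect, since the samples also differed in sex-linked signal and gland and muscle transcripts. It rests on 1 array at day 3, and the count was 834 and 769 without day 14 replicate 1 and 2.

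The lists whose change differed between day 14 and day 3, by camera with a preset correlation, were those that follow, with their median difference on the log2 scale and the adjusted p with an estimated correlation. Gland lists were higher at day 14, acinar by 7.04 (0.269) and granular duct by 13.19 (0.269). Lower at day 14 were proliferation at −3.77 (0.364), cell cycle inhibitors and p53 targets at −0.77 (0.364), Wnt targets at −2.94 (0.160), glycolysis at −0.83 (0.364), sterol synthesis at −1.37 (0.160) and ribosome biogenesis at −0.85 (0.254). FOXO targets were at 0.78 (0.269), ER folding at 0.85 (0.638), ATF4 at 1.10 (0.735) and mitochondrial respiration at 0.41 (0.638). Macrophage genes were at −1.08 (0.396), neutrophil at −6.03 (0.364), T cell at 3.62 (0.472), B and plasma cell at 6.90 (0.364), endothelial at 0.69 (0.638), adipocyte at 1.95 (0.638) and skeletal muscle at 10.19 (0.472). Dim members make some of these sizes uncertain. With them at their bound the medians were 2.56 for T cell, where 8 of 12 members were dim in a group and 1 was called over all genes, 5.32 for B and plasma cell, with 8 of 11 dim, 8.47 for muscle, 12.19 for granular duct and 6.45 for acinar genes. They were −3.49 for proliferation, −2.82 for Wnt targets, −1.36 for sterol synthesis, 0.81 for ATF4 and −1.001 for macrophage genes.

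The return of both gland lists at day 14 could reflect normal gland in the samples, a change of the tumour cells, or the sex of the animals. Sex as the only cause was argued against, since the lower day 14 array exceeded the untreated tumour with Y-linked signal by a median of 13.55 over granular duct genes, against 0.47 between the untreated tumours. Even dilution of untreated tumour RNA was tested on transcripts dim in both normal glands and bright enough in untreated tumour to be measured at 1% of that level, a choice that does not use their day 14 level. All 7 were measured at day 14, and their log2 retained share had an interquartile range of 1.68, against 0.317 between day 14 replicates. The share was 21.5% for Tmc5 and 5.05% for Bpifb9a, but 0.655% to 1.14% for the other 5, so Tmc5 and Bpifb9a set this range. Other tissues were not tested, so dilution stays open. An earlier form over all 52 transcripts bright in untreated tumour and dim in both normal glands gave 1.39, but array floors set it, since 37 were dim on both day 14 arrays. The test for an almost wholly normal sample, added after that value was seen, gave a median kept of 3.50% of the untreated level over the 52. A small tumour share or treatment could give this, and dim ones give only upper limits. Parotid as the only gland tissue was argued against by submandibular transcripts, a median of 1.69 above parotid at day 14. Those of parotid were also a median of 1.67 above submandibular gland. Loss of tumour cells, more normal tissue sampled and change within tumour cells stay open.

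Skeletal muscle transcripts were high in both day 14 arrays and in parotid replicate 2, an untreated normal gland. Muscle tissue in the samples may be the source, since 13 of 14 list members were more than 1 higher on the log2 scale in parotid replicate 2 than in replicate 1, by a median of 5.09. Of the 14 members, 14 were well above background in parotid replicate 2 and in each day 14 array, 8 in each untreated tumour, 6 in parotid replicate 1, 7 at day 3 and 3 in the submandibular gland, and the labels give no step that would remove muscle. Rapamycin as the only cause was argued against, since parotid replicate 2, without rapamycin, exceeded untreated tumour by a median of 6.06. A contribution of rapamycin to the day 14 level, which exceeded parotid replicate 2 by a median of 3.33, stays open.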

How the results depend on the processing

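Keeping outlier spots, the list counts without single arrays and by slide, and differences on slide 2 were chosen only after the results were seen, and the other alternatives were planned. With normexp background correction, 4180 genes differed between untreated tumour and parotid, 5093 between day 14 and untreated tumour, 5 between day 3 and untreated tumour, 1100 between day 14 and parotid and 3073 between untreated tumour and submandibular gland. Quantile normalization gave 6 at day 3 and 668 between the normal glands, and the deposited values gave 2 at day 3. With no filter on dim probes the counts were 15343 for untreated tumour against parotid (22.3% higher), 16629 for day 14 against untreated tumour (75.5% higher), 29 at day 3 and 13385 for untreated tumour against submandibular gland (20.8% higher), and the median of all genes then shifted by −0.97, 1.09 and 0.47 in the first 3 of these. Signal over background limits what can be said of dim genes, whose folds are bounds where no array of a group was well above background.

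With probes well above background on all 8 arrays, 2313 genes differed between day 14 and day 3, 3055 between untreated tumour and submandibular gland and 225 between the normal glands, where fewer genes were tested. Without the intensity trend 2 genes differed at day 3, and C3 was not one of them. Slide as a fixed block gave 0 at day 3, 2266 for untreated tumour against submandibular gland and 118 between the normal glands. Fits to only the arrays of the groups compared gave 0 at day 3, 8709 for day 14 against day 3, 690 for day 14 against parotid, 8082 for untreated tumour against submandibular gland and 81 between the normal glands. The correlation of tumour and day 14 differences was −0.825 with quantile normalization, −0.824 with the deposited values, −0.806 within slide 1 and −0.778 for single arrays that share none. The cause was not tested for these changes.

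Leaving out 1 array gave 3034 to 8630 genes for untreated tumour against parotid, 3736 to 10564 for day 14 against untreated tumour, 0 to 288 for day 3, 769 to 7468 for day 14 against day 3, 0 to 5891 for day 14 against parotid, 2467 to 8224 for untreated tumour against submandibular gland and 9 to 3385 between the normal glands. Counts rose when a parotid array was left out and fell when a day 14 or untreated tumour array was. The parotid arrays correlated at 0.937, against 0.985 and 0.987 in the other replicated groups. The correlation stayed between −0.858 and −0.815.

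The value of a called gene or the camera direction of a called list reversed in 7 cases. With probes well above background on all 8 arrays, untreated tumour against parotid gave −1.57 for Ncam1 and −0.51 for the adipocyte list, whose camera direction changed. At day 3, granular duct genes were at −0.0918 with normexp and fibroblast genes at −0.22 without untreated tumour replicate 2, and up to 1.75 without replicate 1. Between the normal glands, without parotid replicate 1, proliferation was at 0.18 and B cell at 0.14, with muscle at −5.47. Without parotid replicate 2 muscle was at 0.74, with proliferation at −1.13 and B cell at −4.36. The median of a called list also changed sign, without a change of camera direction and with the call lost, in 3 cases. These were proliferation at day 3 against untreated tumour, 0.0302 with slide as a fixed block, ATF4 at day 14 against parotid, 0.17 without parotid replicate 2, and Wnt targets between the normal glands, −0.00416 with normexp. The cause was not tested. Besides the reversed ones, 1889 list values, called or not, stayed on their side of the threshold and 69 gained a call. Another 178 lost a call, among them these 3 and 108 with an estimated correlation. Of named gene values, called or not, 4535 stayed on their side, 414 lost a call and 28 gained one.

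Comparisons with day 3 or submandibular gland have no value within slide 1, which holds neither. No paired analysis was possible because the groups share fewer than 2 replicate numbers in the labels. No group had 3 arrays, so other splits of the samples were not counted.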

Other observations

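Changes from untreated tumour at day 3 and 14 correlated over genes at r = 0.535 (covariance 1.00). Simulated unchanged groups that share the tumour arrays gave means of 0.409 (0.124).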
